A study of Mus musculus with 6 samples.

How the data were processed

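Corneas of naive female mice on a mixed 129S2 and C57BL/6 background were cut anterior to the limbus, digested with collagenase A and DNase I and depleted of dead cells, per the labels. Mice lacked the miR-183/96/182 microRNA cluster (KO) or were wild type (WT). Droplet libraries (10x Genomics 3' chemistry) were made from whole cornea at 2 and 6 months, and at 6 months also from cornea-resident immune cells enriched on magnetic beads for CD45, a surface protein of blood-derived cells (called CRIC here). Each of the 6 groups held 1 library. No source used here states that the libraries came from separate animals, so no p-value measures more than the spread between these samples. The labels give no replicate numbers that tie WT to KO samples.

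The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger on build mm10, with no normalization. Per the file headers the version was 6.0.1, while the processing notes name version 2.1.1. Aligner settings and the annotation release are not given in the sources used here. The matrices list all barcodes over 31053 features and were not filtered to cells. The labels name the second version of the kit, and the libraries list 559798 to 2214882 barcodes.

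A barcode was kept as a cell with at least 500 UMIs, at least 250 genes, at most 20% mitochondrial UMIs, and a profile that differed from the free RNA of its library (barcodes of at most 100 UMIs) in a Monte Carlo multinomial test at an adjusted p of 0.01. Scrublet (expected rate 0.06) marked 0 cells in each of the 4 cornea libraries, of 11123 to 15087 cells, so it did not work there and doublets of those libraries were not removed. In the CRIC libraries it marked 28 WT and 55 KO cells (0.836% and 1.14%), which were left out. Clusters whose best class was keratocyte and that also showed epithelial or macrophage markers were kept out of all classes. Clusters whose best class was epithelial stayed in that class even where they also showed keratocyte markers. Among them were clusters of 2689, 2540, 1173 and 764 cells.

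Counts were scaled to 10000 per cell and log-transformed. With 2000 variable genes, 30 principal components and 15 neighbours, cells of all libraries were clustered together by Leiden at resolution 1.0 without integration (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters were named from markers fixed before the data were examined, needing at least 3 markers each seen in over 20% of cells. The immune clusters were clustered again among themselves and named by the same rule. Names therefore mean cells like that type. Clusters led by Psca, and an immune cluster led by Arg1, Fn1, Spp1 and Fabp5, stayed unnamed because markers of another class outnumbered those of their best class among their top genes. In the immune cluster this was the monocyte marker Fn1 alone against 0 macrophage markers, though 9 macrophage markers were each seen in over 20% of its cells. In those led by Psca it was Plac8 alone, also a monocyte marker, against 0 epithelial ones. A cluster made mostly of 1 library may be that library and not a type. Leiden results depend on the random seed and on the numerical settings of the processor libraries. Both were fixed, and 2 full runs with them gave identical results. An earlier run with other numerical settings gave another partition and other gene counts, so another seed was added as an alternative after the data were seen.

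Raw counts were summed per library and class and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 (TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). For macrophage-like and all immune cells the genotype test used all 6 libraries with the pair (cornea 2 months, cornea 6 months, CRIC 6 months) as a block, leaving 2 residual degrees of freedom. For keratocyte-like and epithelial cells the genotype and age tests used the 4 cornea libraries with both factors, leaving 1 residual degree of freedom. Leaving 1 library out of these 4 left no residual degree of freedom with both factors, so such fits had the tested factor alone, with the lone library of a group assumed to vary like the other group. Leaving 1 library out of the 6 kept the pair as a block. Its partner then added nothing to the genotype estimate, which rested on the other pairs. Standard errors (SE) are the log2 fold divided by the square root of F. The variance behind F is partly shared across genes, so an SE can be far below a gene's own spread between pairs. No test of single genes or shares was made within a pair, since each group held 1 library. There, summed counts scaled to a common library size (CPM) carry 95% exact Poisson intervals and shares of cells carry 95% exact (Clopper-Pearson) binomial intervals. Both cover counting error only. A count of 0 was set to a floor of 3 counts per library for ratios, which are then bounds.

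Genes were named by a rule fixed before the data were examined. The rule took up to 15 higher and 15 lower genes past the test with the same sign in every pair, by size of fold. Where these were fewer than 20, it added up to 10 per direction with at least 50 CPM, the same sign and the largest smallest ratio over pairs, called not past the test. Within a pair it took the 10 highest and 10 lowest ratios at 50 CPM or more. It also took list members past the test, otherwise those of largest ratio at 20 CPM or more, and the genes flanking the deleted cluster. Mitochondrial and ribosomal protein genes were not named. A result on 1 gene of the rule is not reported here.

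The gene lists, fixed before the data were examined, were MHC class II presentation, type I interferon response, inflammatory cytokines and chemokines, resident tissue macrophage, complement, phagocytosis and oxidative burst, proposed or reported targets of the 3 microRNAs, immediate early, heat shock, cell cycle, basal and limbal epithelium, differentiated corneal epithelium, clock, stromal extracellular matrix, axon guidance, mast cell effector and T cell effector genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and within pairs by the percentile of the list's median log2 ratio among 10000 random lists matched on expression. Genes with a seed match of miR-96, miR-182 or miR-183 in the 3' UTR were set against 10000 random gene sets matched on expression and UTR length.

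Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, at least 1000 UMIs, doublets kept, Leiden resolution 0.5, each cell thinned to 500 UMIs, other model terms, leaving out pairs and libraries, and for shares a knee rule, no ambient test, 10% mitochondrial UMIs and classes from each cell's own markers. No cell fell below 500 UMIs, so thinning left out 0 cells in every group. The designs were tested on simulated data with 200 changed genes. Of 4-fold changes 92.6% to 97.0% were recovered and of 2-fold changes 30.3% to 64.6%, with 2 to 6 false calls. The simulation gave all genes a common dispersion and no effect of pair or age, nor a genotype effect differing between pairs. Its false calls therefore do not bound those in the real libraries. Lists with no planted change fell above the central 95% of random lists in 0 and below it in 2 of 40 simulated lists. Figures were drawn with matplotlib 3.10.9.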

Results

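Gene expression of single cells was measured in 6 libraries of mouse cornea, 1 per group. Whole cornea was taken at 2 months and at 6 months of age, and CD45-enriched immune cells (CRIC) at 6 months, each from WT and from KO mice. The WT and KO libraries held 67475723 and 78915074 UMIs at 2 months, 117613142 and 33127813 in whole cornea at 6 months, and 9827933 and 23141410 in CRIC. They gave 14525 and 13400 cells at 2 months, 15087 and 11123 in cornea at 6 months, and 3322 and 4772 in CRIC. Median depth per cell in WT and KO was 3293 and 4112 UMIs at 2 months, 5494 and 1862 in cornea at 6 months, and 1151 and 2126 in CRIC, so the KO library was the shallower of the 6-month cornea pair and the deeper of the others. Barcodes of free RNA held 7.58% to 9.12% of all UMIs in the cornea libraries and in the KO CRIC library 8.33%, against 16.2% in the WT CRIC library. A ratio within 1 pair has no replicate check.

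The deleted microRNA cluster lies on chromosome 6 of build mm10, with Mir182 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737. None of the 3 is a feature of the deposited matrices, so the deletion could not be checked in any library. The flanking genes are Nrf1 (30047988 to 30153458), which encodes a transcription factor of mitochondrial genes, and Ube2h (30211289 to 30304539), which encodes a ubiquitin-conjugating enzyme. Between genotypes Nrf1 did not pass the test in keratocyte-like cells (log2 0.18 ± 0.230 SE, 4 libraries) or epithelial cells (-0.08 ± 0.185), nor did Ube2h (0.05 ± 0.251 and -0.10 ± 0.146). In all immune cells of CRIC, Nrf1 stood at 9.49 CPM in WT (5.31 to 15.65) and 20.3 in KO (16.5 to 24.8), and Ube2h at 33.5 and 28.4. Nrf1 stood at 5.53 and 23.9 CPM in cornea at 6 months, on 2 and 9 counts. At 2 months it stood at 9.14 and 9.43, on 2 counts each. As Nrf1 and Ube2h lie outside the deleted part, they check nothing about the labels. A second check of the labels used sex, as all mice are labelled female. The library labelled KO at 2 months held 3077 UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, against 0 to 2 in the other libraries, and 545.6 CPM of Xist, which silences an X chromosome in females, against 616.9 to 905.5. Of its 4691 cells of at least 5000 UMIs, 962 had Y-linked UMIs alone, 2357 Xist alone, 179 both and 1193 neither. Y-linked and Xist UMIs thus fell mostly in different cells of that library. Every 2-month genotype ratio and every age ratio within KO carries this difference. So does every test of genotype or age that uses this library, which includes all the main ones.

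The first comparison asked which immune cells live in the cornea and whether their shares differ without the cluster. Immune cells made up 1.36% of WT and 1.43% of KO cells at 2 months (95% intervals 1.18 to 1.56 and 1.24 to 1.65), a difference not detectable at this depth. At 6 months they made up 1.27% in WT (1.09 to 1.46) and 2.95% in KO (2.64 to 3.28), and after CD45 enrichment 52.0% in WT and 55.5% in KO. The KO minus WT difference in cornea at 6 months, 1.68 points, was 1.01 with at least 1000 UMIs per cell and 0.71 with the knee rule, and that in CRIC, 3.43, was 22.92 and 0.69. Macrophage-like cells, which take up debris and microbes, were 100% of 197 immune cells in WT and 95.8% of 192 in KO at 2 months. At 6 months they were 93.7% of 191 in WT and 28.7% of 328 in KO, and in CRIC 96.9% of 1728 in WT and 71.2% of 2646 in KO. The class took in a cluster led by Ccl17, Asgr2 and Mgl2 with a macrophage marker score of -0.51, below the mean of the immune clusters. It held 10.06% of the class in WT and 20.2% in KO cornea at 6 months, and 7.70% and 6.95% in CRIC. With predicted doublets kept, a cluster led by Ccl17 and Asgr2 stayed unnamed, with the dendritic marker Cd209a among its top genes. Dendritic-like cells may thus sit in the class. Neutrophil-like cells were 1.05% (0.127 to 3.73) in WT and 4.88% (2.81 to 7.80) in KO at 6 months, and 0.579% (0.278 to 1.06) and 5.06% (4.26 to 5.97) in CRIC, while 0 were seen at 2 months, which allows up to 1.52% in WT and 1.56% in KO (3 counts of the total). The exact 95% intervals of a count of 0 reach 1.855% and 1.903% there. With at least 1000 UMIs per cell their KO minus WT difference in cornea at 6 months was -1.28 points and with the knee rule 0, against 3.83. T or innate lymphoid-like cells, some with Trdc and Il17a, were 2.08% (1.46 to 2.87) in WT and 7.45% (6.47 to 8.51) in KO CRIC, and 3.14% and 5.18% in cornea at 6 months.

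An immune cluster led by Arg1, Fn1, Spp1, Fabp5 and Pdpn could not be named, and most of the shift of macrophage-like shares went with it. It held 0% and 1.04% of immune cells of WT and KO at 2 months, 2.09% and 61.3% in cornea at 6 months, and 0.405% and 16.3% in CRIC. Together with macrophage-like cells it made 95.8% and 89.9% of immune cells in cornea at 6 months and 97.3% and 87.5% in CRIC. As most of its cells came from the KO libraries of 6 months, it may be those libraries and not a type. The 500-UMI minimum acts on these shares because immune cells were shallow, with medians of 1643 UMIs in WT and 1044.5 in KO cornea at 6 months and 791 and 1446 in CRIC. With at least 1000 UMIs per cell and clustering anew, the KO minus WT difference for macrophage-like cells was -5.66 points in cornea at 6 months and -2.52 points in CRIC, against -65.06 and -25.69. With the predicted doublets of CRIC kept, which draws all clusters anew, it was 2.59 and -7.27 points, and a cluster led by Arg1, Fn1 and Spp1 was then named macrophage-like. Fn1, a monocyte marker, was then not among the top genes used for naming, while in the main run it alone kept that name from the cluster. These shares thus rest on which clusters take the name. The enrichment on CD45 and the dead cell removal set the share of immune cells in CRIC.

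**Figure D1:**
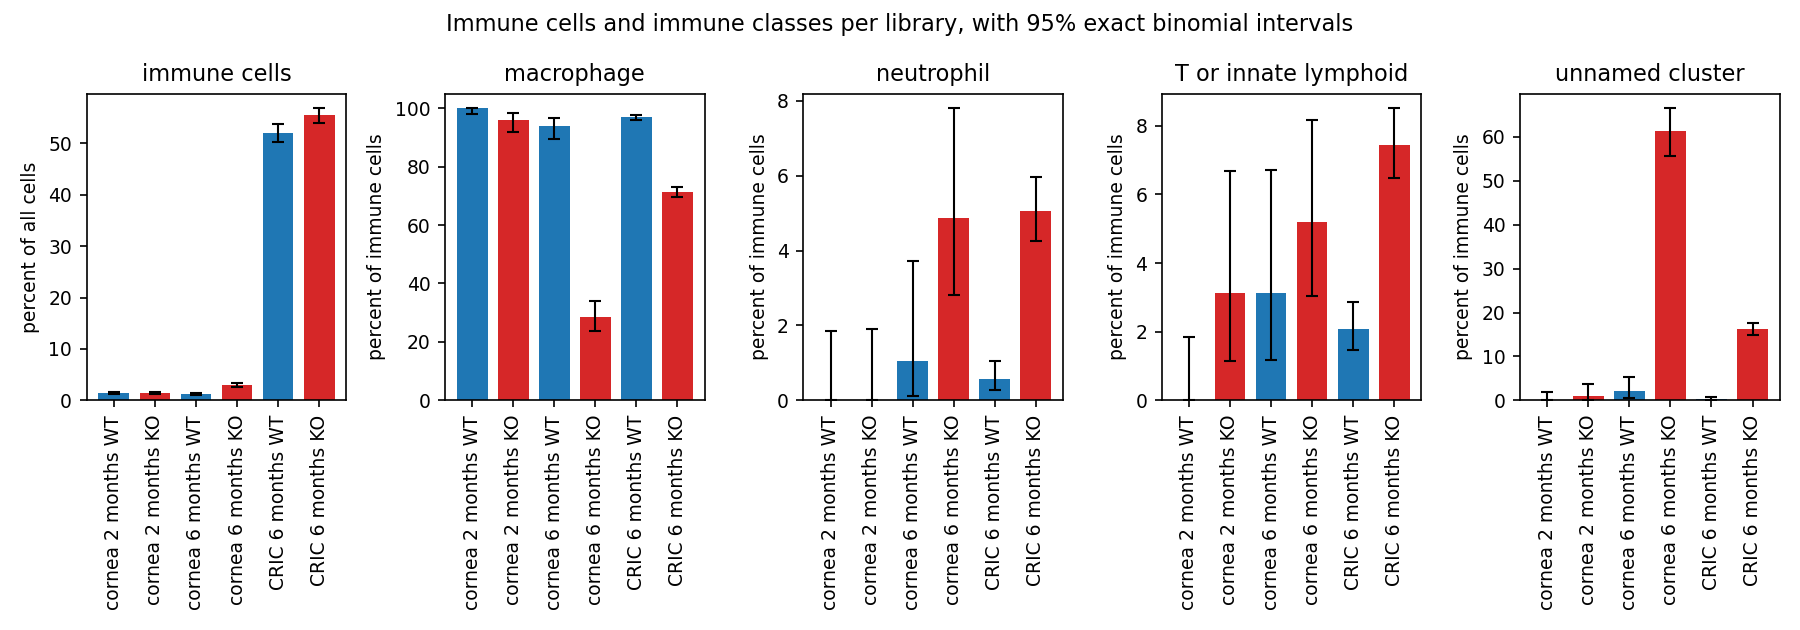
Bars give the percent of all cells that were immune and, in the other panels, the percent of immune cells in each class, for WT (blue) and KO (red) libraries of the 3 pairs, with 95% exact binomial intervals covering counting error only. The unnamed cluster reached 61.3% and neutrophil-like cells 4.88% in the KO cornea library at 6 months.

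Across all immune cells, Fn1, which encodes the matrix protein fibronectin, rose in KO by a log2 fold of 3.82 ± 0.408 (SE, 3 WT and 3 KO libraries, adjusted p = 1.43e-07), with pair values of 0.63 (on 2 and 3 counts), 4.92 and 3.56. Fabp5 (ENSMUSG00000027533), a carrier of fatty acids, rose by 3.28 ± 0.354 (adjusted p = 1.43e-07, higher in 3 of 3 pairs, but below its free-RNA level in KO at 2 months, at 37.7 against 73.7 CPM, and in KO CRIC, at 143.7 against 191.9), and Spp1, the secreted protein osteopontin, by 2.92 ± 0.311 (adjusted p = 1.43e-07, 3 of 3 pairs). S100a9, a subunit of the neutrophil protein calprotectin, rose by 2.39 ± 0.392 (adjusted p = 0.000583), with 3.51 and 2.19 in the pairs of 6 months and no direction at 2 months (2 WT and 0 KO counts). Ltb, a lymphocyte cytokine, rose by 2.56 ± 0.389 (adjusted p = 0.000166, 3 of 3 pairs, at 2 months on 0 and 5 counts). Mgl2, a lectin of macrophages and dendritic cells, fell by 2.04 on the log2 scale (± 0.391, adjusted p = 0.00364), and its pair values were -2.48, -3.88 and -0.71.

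The edgeR test on all immune cells called 25 genes higher and 2 lower in KO of 4391, with 273 at an unadjusted p under 0.05, and the DESeq2 Wald test called 13. DESeq2 gave no adjusted p for 3150 of these genes. Other genes that rose, each higher in 3 of 3 pairs, included Pgk1 (1.75), Tnfaip2 (1.48), Furin (1.47), Lmna (1.40), S100a4 (1.28) and Aldoa (1.14, ENSMUSG00000030695). Pdpn (2.64) rose as well, with 2 WT and 0 KO counts at 2 months, where a floor of 3 counts alone gives it the sign of the other pairs, as for S100a9. Emilin2 (1.80), Clec5a (1.41), Cd3g (1.24), Cd44 (1.12), Ccl4 (-0.88), Batf3 (-1.06) and Ighm (-1.06) had the same sign in every pair and did not pass. The count was 122 without the 2-month WT library, 120 without the 2-month KO library, 14 without the 6-month WT cornea library, 9 without the 6-month KO cornea library, 16 without WT CRIC and 14 without KO CRIC. Leaving out either library of a pair removes what that pair says on genotype, so these are not separate checks of single libraries. The summed counts move with the mix of immune classes, and Fn1, Fabp5, Spp1 and Pdpn also lead the unnamed cluster while S100a9 marks neutrophils.

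The share of immune cells with a UMI, with each cell thinned to 500 UMIs, was set against that of epithelial cells as a guide to free RNA. For Spp1 it was 5.24% in WT and 25.6% in KO cornea at 6 months, against 0% in epithelial cells of both, and 14.7% and 38.4% without thinning. In CRIC it was 2.78% and 13.5%, against 0% in epithelial cells, and 5.15% and 26.0% without thinning. For Arg1, which encodes arginase, it was 0.524% and 19.5% in cornea at 6 months, against 0.728% and 1.21% in epithelial cells (without thinning 1.05% and 33.5%, against 4.52% and 4.92%), so the WT share did not exceed that of epithelial cells. In CRIC 0% and 4.8% of immune cells had Arg1, against 1.26% and 2.43% of epithelial cells (without thinning 0.116% and 11.3%, against 13% and 28.5%). The thinned WT CRIC intervals, 0 to 0.213% of immune and 0.463% to 2.72% of epithelial cells, did not overlap. Free RNA reaching both classes alike would not give this, so the epithelial share is no measure of free RNA for Arg1. Median depths in immune and epithelial cells were 1643 and 5985 UMIs in WT and 1044.5 and 2648 in KO cornea at 6 months, and 791 and 3395 in WT and 1446 and 6350 in KO CRIC.

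**Figure D2:**
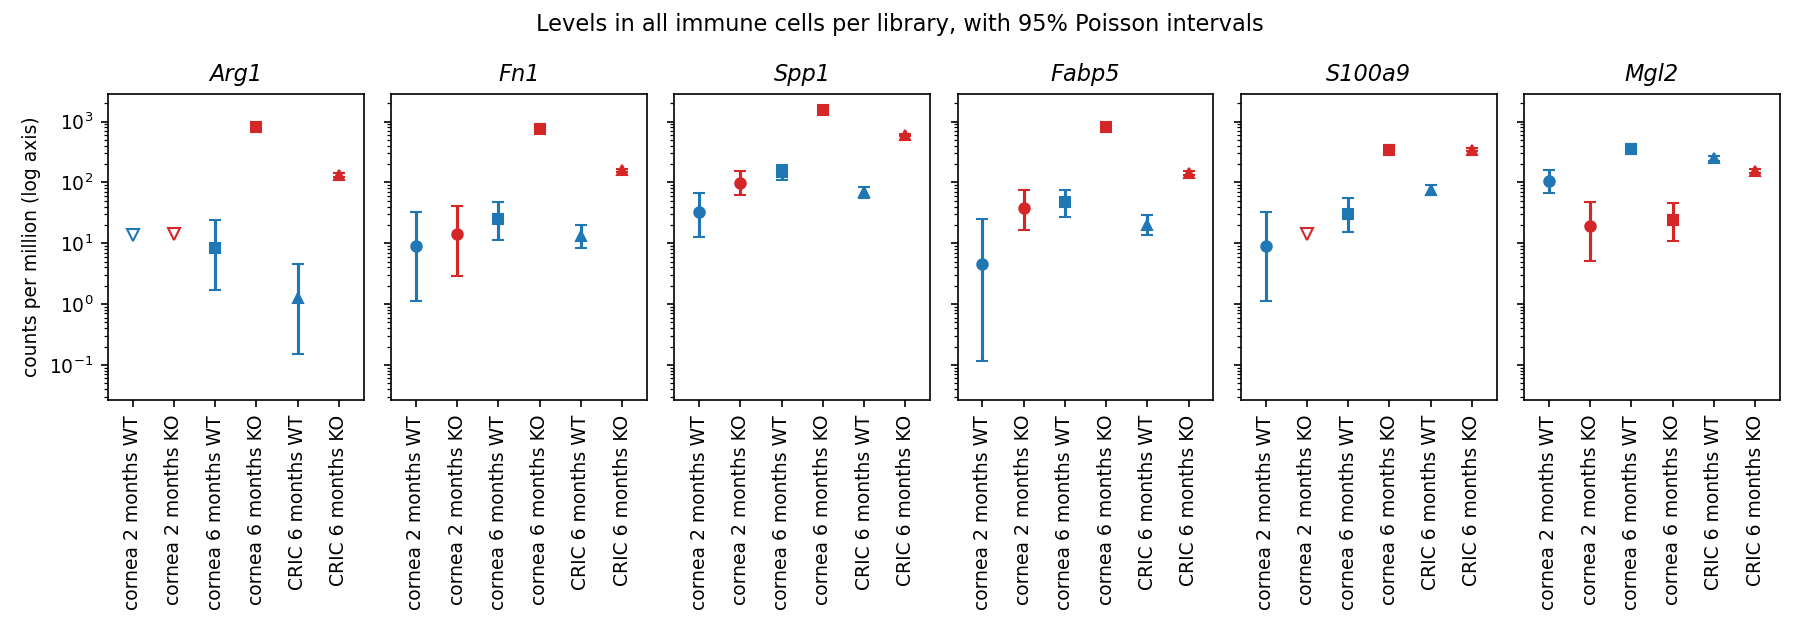
CPM of 6 genes summed over all immune cells is drawn on a log axis for WT (blue) and KO (red) libraries, as circles for 2-month cornea, squares for 6-month cornea and triangles for CRIC, with 95% Poisson intervals and open downward triangles at a floor of 3 counts where the count was 0. Arg1 stood at 8.29 CPM in WT and 821.8 in KO cornea at 6 months, and Mgl2 at 353.7 and 23.9.

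Within macrophage-like cells alone, Fabp5 rose in KO by a log2 fold of 2.49 ± 0.421 (SE, 3 WT and 3 KO libraries, adjusted p = 1.12e-05), with pair values of 2.92 (on 1 and 7 counts, with KO at 34.6 CPM against 73.7 in free RNA), 2.97 and 2.35. Fn1 rose by 2.43 ± 0.511 (adjusted p = 0.00225), with 0.70 (2 and 3 counts), 2.70 and 2.78. The third call was Arg1, outside the naming rule and chosen after its values were seen, at 8.66 CPM in WT and 157.9 in KO cornea at 6 months and 1.31 and 47.9 in CRIC, with 0 counts in both 2-month libraries. Plxnb2 (1.45), a receptor of semaphorins, Clec5a (1.27), a receptor of myeloid cells, and F13a1 (1.84), a clotting factor subunit, were higher in 3 of 3 pairs and did not pass.

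Of 3410 genes in macrophage-like cells, edgeR called 3 higher and 0 lower, with 80 at an unadjusted p under 0.05, and DESeq2 called 2 with 25. Without WT CRIC or without KO CRIC edgeR called 0 higher and 1 lower, so none of the 3 calls was kept, while the folds of Fabp5 (2.79 and 2.78) and Fn1 (2.08 and 1.92) kept their sign. It called 3 higher and 1 lower without either 2-month library, and 2 higher without either 6-month cornea library. Another Leiden seed, which repeats the clustering from another starting point and was added after the data were seen, gave 0 genes. In KO CRIC, macrophage-like cells held Fabp5 at 90.5 CPM against 191.9 in free RNA, Fn1 at 81.0 against 84.5 and Arg1 at 47.9 against 50.8, and in KO cornea at 6 months Fn1 at 169.2 against 233.5, so free RNA may hold part of these rises. In all immune cells of KO CRIC, Krt14 (3.39 against 124.5), Chil1 (3.81 against 35.3) and Serpina3n (0.212 against 22.8), genes of other cell types, lay far below free RNA. Timp1 (8.48 against 8.30) and Slpi (10.6 against 6.22) did not. Saa3 (8.9 against 42.5) and Lcn2 (4.66 against 21.8) lay below it. The values below free RNA argue against it as the main source of the rises in KO CRIC, while those of Timp1 and Slpi do not. All come from all immune cells, not from macrophage-like cells alone. Fn1 lay below free RNA in this class in all 6 libraries. In cornea libraries a macrophage-like cluster led by the epithelial genes Psca, Asprv1 and Lce3a held 43.6% to 78.8% of the class. In CRIC a cluster led by H2-Aa was the largest in WT (46.3%), and clusters led by Bcl6 and Gpr34 (31.4%) and by Lpl (24.5%) were the largest in KO.

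In the CRIC pair alone, genes above WT in KO macrophage-like cells were Spp1 (log2 2.28, though in cornea at 6 months it stood at 153 CPM in WT and 67.7 in KO, on 53 and 6 counts), Lpl (2.09, 95% interval 1.56 to 2.67), a lipase, and Ccl17 (2.03, 1.44 to 2.67), a chemokine. Ccl17 also led the cluster of the class that may hold dendritic-like cells. Siglech, a lectin, was at -1.44 (-1.88 to -1.01) and Slc15a2, a peptide transporter, at -1.44 (-1.89 to -0.99). In all immune cells of that pair Areg, a growth factor, was at 2.79 (2.11 to 3.56) and Ptgs2, an enzyme of prostaglandin synthesis, at 2.78 (2.03 to 3.63). In cornea at 6 months, all immune cells had Irgm1, an interferon-induced GTPase, at -6.21 (-11.53 to -3.68) and Ccl17 at -4.76 (-10.11 to -2.15), each on few counts. The median of all genes lay at 0.17 in cornea at 6 months and 0.12 in CRIC for all immune cells.

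In keratocyte-like cells, the fibroblasts of the corneal stroma, Saa3 (ENSMUSG00000040026), an acute-phase protein, rose in KO by a log2 fold of 6.72 ± 0.623 (SE, 2 WT and 2 KO libraries, adjusted p = 3.31e-23), with 1.77 at 2 months and 8.40 at 6 months. This SE, with variance shared across genes, is far below the gap between the pair values, and the p-value does not measure that gap. Lcn2, an iron-binding antimicrobial protein, rose by 5.44 ± 0.463 (adjusted p = 1.19e-27, pair values 0.67 and 6.79), and Chil1, a chitinase-like glycoprotein, by 3.77 ± 0.434 (adjusted p = 2.16e-14, 1.42 and 6.10). Lama4 and Lamb1, laminin chains of basement membranes, rose by 2.18 and 2.14. Cxcl10, a chemokine induced by interferon, fell by 3.02 on the log2 scale (± 0.397, adjusted p = 7.17e-11), with -6.92 and -0.31 in the pairs and a reversed 0.96 in the 6-month pairs only, and Nr4a2, an early-response nuclear receptor, fell by 1.03 (± 0.247, adjusted p = 0.0124), with -1.33 and -0.58. A cluster led by Cxcl10 held 42 cells in WT and 1 in KO at 2 months (0.408% and 0.0122% of the class), so few cells may carry the value there. For Saa3 most of the rise came from 6 months, as it stood at 0.427 CPM in WT and 1.45 in KO at 2 months, and at 10.01 and 3384.6 CPM at 6 months. Keratocyte-like cells of the KO cornea library at 6 months had the highest median shares of mitochondrial (3.03%, against 2.18% in WT) and rRNA-like UMIs (5.31%, against 3.42%) in this class, and whether RNA quality plays a part was not tested. Ccl7 (-0.53 and 3.38) passed the test with opposite signs in the pairs.

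The edgeR test called 31 genes higher and 15 lower in KO keratocyte-like cells of 14143, with 367 at an unadjusted p under 0.05, while DESeq2 called 0 with 126 and edgeR over all 6 libraries with the pair as a block called 0. In fits of genotype alone, the count was 3 without the 2-month KO library, 3 without the 6-month WT library, 0 without the 2-month WT or the 6-month KO library and 0 with all 4. Without the 6-month KO library, where such a fit sets 2-month KO against WT of both ages, Saa3 was at -1.84, Lcn2 at -1.64 and Chil1 at -0.21. Other genes higher in both pairs were Ctsc (4.53), Ereg (3.06), Mpeg1 (2.02), Ltbp2 (1.76), Cp (1.74) and Clu (1.59), and Nr4a3 (-0.89) and Ramp2 (-0.88) were lower. The largest keratocyte-like cluster differed between libraries. A low-UMI cluster led by Gm26917 and Lars2 was the largest in WT at 2 months (35.3%), one led by Tnmd and Crabp1 in KO at 2 months (30.2%), one led by Crabp2 and Nr4a2 in WT at 6 months (28.5%), and one led by Saa3, Chil1, Mmp3 and Lcn2 (27.2%) and the low-UMI one (27.0%) in KO at 6 months.

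With each keratocyte-like cell thinned to 500 UMIs, Saa3 was seen in 0.108% of WT and 20.5% of KO cells at 6 months, against 0% and 0.836% of epithelial cells, and in 0.504% and 23.9% without thinning. Lcn2 was seen in 0.0900% and 9.82%, against 0% and 0.279% of epithelial cells, and in 0.567% and 17.3% without thinning. Chil1 was seen in 1.35% and 24.0%, against 0.194% and 0.557% of epithelial cells, and in 8.10% and 30.1% without thinning. Median depths were 5180.5 UMIs in WT and 1733 in KO keratocyte-like cells, and 5985 and 2648 in epithelial cells. In CRIC, Saa3 was seen in 0 of 894 WT and 1.07% of KO keratocyte-like cells (0.224% and 2.76% without thinning), with 0% in epithelial cells, at median depths of 2000 and 4206 UMIs against 3395 and 6350.

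**Figure D3:**
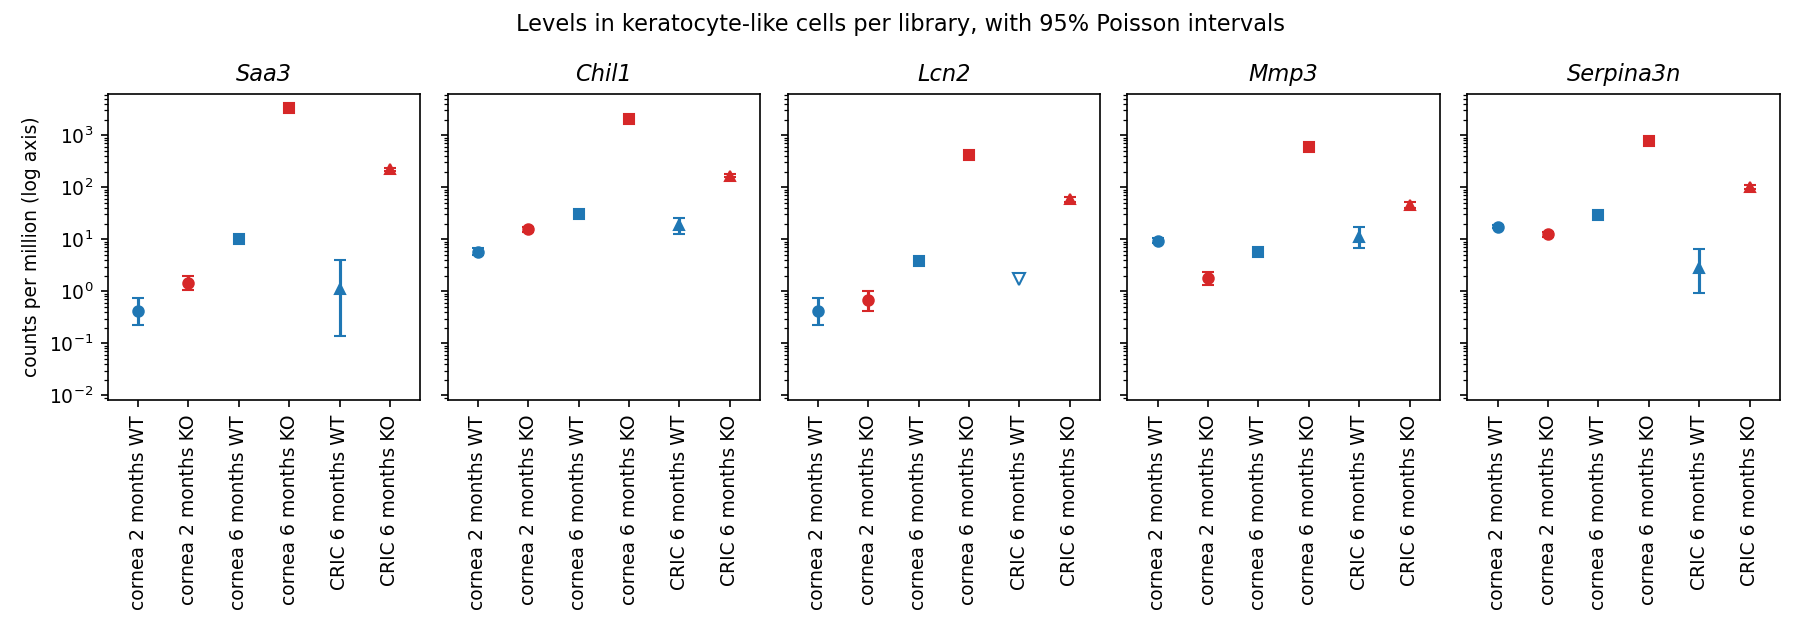
CPM of 5 genes summed over keratocyte-like cells is drawn on a log axis for WT (blue) and KO (red) libraries, as circles for 2-month cornea, squares for 6-month cornea and triangles for CRIC, with 95% Poisson intervals and open downward triangles at a floor of 3 counts where the count was 0. Chil1 stood at 30.5 CPM in WT and 2086.6 in KO cornea at 6 months.

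Within the 6-month cornea pair, KO keratocyte-like cells had Mmp12, a macrophage elastase, at 196.4 CPM against 0.0677 in WT (log2 11.50, 10.15 to 13.38), Timp1, an inhibitor of such proteases, at log2 7.77 (7.35 to 8.22), Mmp3 at 6.69 (6.53 to 6.85) and Serpina3n, a protease inhibitor, at 4.72 (4.65 to 4.79). Gstp1, an enzyme of detoxification, was at -2.32 (-2.56 to -2.09). In the CRIC pair Saa3 was at 7.60 (5.75 to 10.65), Serpina3n at 5.14 (3.91 to 6.77) and Chil1 at 3.17 (2.66 to 3.72), and Lcn2, at 0 counts in WT, was above it by a log2 of at least 5.11 against a floor of 3 counts per library. At 2 months KO was above WT for Tsc22d3 (0.99, 0.95 to 1.03) and Cebpd (0.97, 0.91 to 1.04), both induced by glucocorticoids, and for the metallothionein Mt2 (0.83, 0.74 to 0.93). KO was below WT for the chemokine Ccl2 (-1.81, -1.95 to -1.66) and for Nr4a1 (-0.84, -0.91 to -0.77). The median of all genes lay at 0.15 in the 6-month cornea pair.

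In epithelial cells, of the outer layer of the cornea and without the unnamed clusters led by Psca, no gene passed the test between genotypes. Those clusters, tested only after the data were seen, gave 34 genes higher and 7 lower in KO over the 4 cornea libraries. Psmb8, an immunoproteasome subunit (log2 0.72 ± 0.205 SE, 2 WT and 2 KO libraries, adjusted p = 0.928), Ly6e, an interferon-induced surface protein (0.63 ± 0.164), and Sfn, a keratinocyte 14-3-3 protein (0.45 ± 0.211), were higher in KO in both pairs. The stromal genes Kera (-1.50 ± 0.364), Lum (-1.41 ± 0.441) and Dcn (-1.43 ± 0.483), which encode proteoglycans of keratocytes, were lower in both pairs, as were Fn1 (-0.88 ± 0.139) and Mgp (-1.20 ± 0.218), each at an adjusted p of 0.928. The proliferation gene Mki67 (-0.57) and the limbal gene Gpha2 (-0.63) were lower in both pairs. The edgeR test called 0 of 12179 genes, with 544 at an unadjusted p under 0.05, and DESeq2 called 1 with 168. In fits of genotype alone, the count was 26 without the 2-month WT library and 2 without the 6-month WT library. Another Leiden seed gave 11 genes higher and 41 lower, so the count of 0 depends on which cells are called epithelial. In whole cornea the largest epithelial cluster was led by Gsta2 and Muc15 at 2 months and by Wfdc2 and Krt14 at 6 months. In CRIC it was led by Dsp and Col17a1 in WT (34.2%) and by Krt15 and Krt6a in KO (37.4%).

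Within single pairs, Isg15, a ubiquitin-like protein induced by interferon, was lower in KO epithelial cells at 2 months (log2 -0.77, -0.89 to -0.65) and higher at 6 months (1.53, 1.28 to 1.77) and in CRIC (1.92, 1.58 to 2.27). Fos and Atf3, early-response genes, were at 0.67 (0.63 to 0.72) and 0.71 (0.55 to 0.88) at 2 months. At 6 months Fabp5 was at 2.11 (2.04 to 2.18), and Angptl7 and Dcn, made by keratocytes, at -3.19 (-3.44 to -2.95) and -2.77 (-2.84 to -2.70). In CRIC Krt13, a conjunctival keratin, was at 1.55 (1.42 to 1.68) and Mki67 at -1.33 (-1.64 to -1.03). The make-up of the class differed there, as the cluster led by Krt15 and Krt6a held 17.4% in WT and 37.4% in KO and that led by Mki67 9.02% and 4.59%. In cornea at 6 months the cluster led by Gsta2 and Muc15 held 13.6% in WT and 28.9% in KO. The median of all genes lay at -0.21 in the 6-month cornea pair.

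Age was compared within the cornea libraries, 2 of 2 months and 2 of 6 months. The 2-month KO library among them held Y-linked UMIs, which the others all but lacked. In epithelial cells the chemokine Cxcl1 rose from 2 to 6 months by a log2 fold of 2.49 ± 0.225 (SE, adjusted p = 0.00341), higher in 2 of 2 genotypes. The basal keratin Krt14 rose by 1.81 ± 0.1999 (adjusted p = 0.00642, 1.56 and 1.99), and the cell cycle genes Cdkn3 by 2.11 ± 0.185 and Pttg1 by 1.74 ± 0.156, both at an adjusted p of 0.00341 and higher in 2 of 2 genotypes. Ttc36 fell by 2.32 on the log2 scale (± 0.163, adjusted p = 0.00341, -2.44 and -2.22), Cited4, a transcriptional coactivator, by 3.35 (± 0.322, adjusted p = 0.00404), and Cyp4a12a, an enzyme of fatty acid oxidation, by 2.78 (± 0.285, adjusted p = 0.00516), each in 2 of 2 genotypes. Ube2h, next to the deleted cluster, fell by 0.90 with age (± 0.146, adjusted p = 0.0277, -0.74 and -1.14).

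Of 16 cell cycle genes 11 rose in epithelial cells with age and 0 fell, among them Ube2c (1.62), Birc5 (1.53), Mki67 (1.14) and Top2a (1.12). An epithelial cluster led by Mki67, Cenpf and Top2a held 5.84% of the class in WT and 4.12% in KO at 2 months and 14.2% and 10.03% at 6 months. Of the differentiated epithelium genes Dsg1a (-1.10) and Cldn4 (-0.93) fell, and of the early-response genes Fosb (1.34) rose. The edgeR test called 95 genes higher and 166 lower at 6 months of 12179, with 1909 at an unadjusted p under 0.05, and DESeq2 called 173, with no adjusted p for 2834 genes. In fits of age alone, the count was 288 with all 4 libraries, 152 without the 2-month WT library, 217 without the 2-month KO library, 1557 without the 6-month WT library and 2142 without the 6-month KO library. Another Leiden seed gave 1163 genes with the same model, so the count is far from fixed. Each age had its own libraries, so age cannot be told apart from the preparation.

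**Figure D4:**
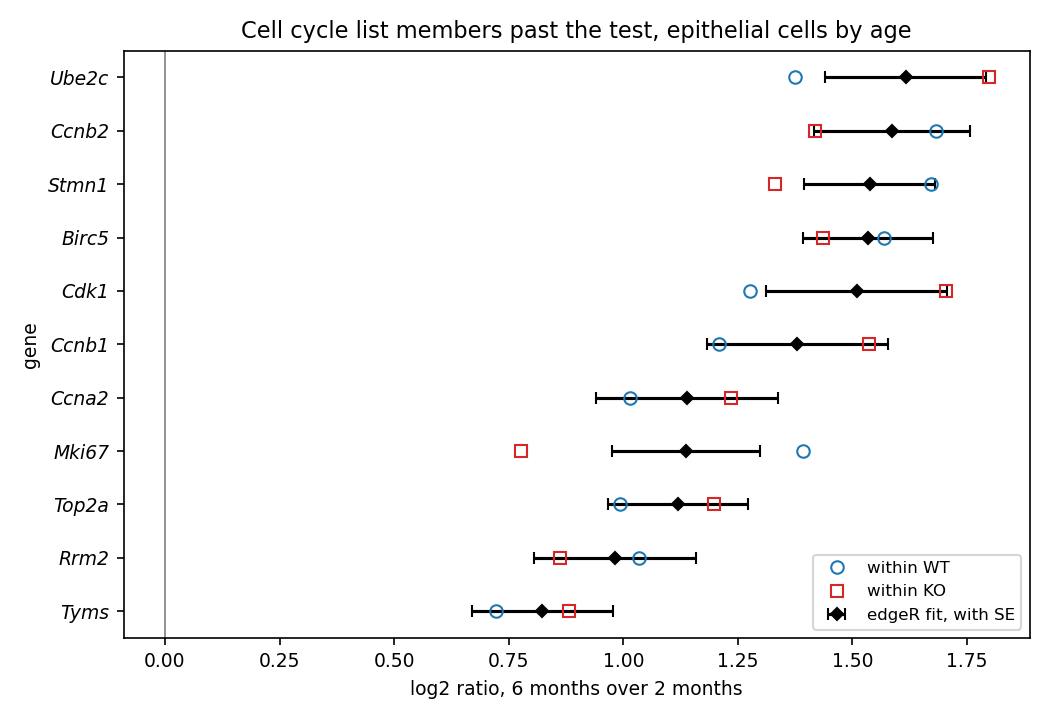
The x axis gives the log2 ratio of 6 over 2 months in epithelial cells for the 11 cell cycle genes past the test, as edgeR folds with their SE (black diamonds), the ratio within WT (open circles) and within KO (open squares). All 11 lay above 0, from 0.82 for Tyms to 1.62 for Ube2c.

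In keratocyte-like cells Klra8 and Klra4, receptors of the Ly49 family known from natural killer cells, rose with age by 3.83 ± 0.277 (SE, 2 and 2 libraries, adjusted p = 1.58e-39) and 3.58 ± 0.275 (adjusted p = 5.66e-35), with 3.86 and 4.06 within WT and KO for Klra8 and 3.54 and 3.88 for Klra4. As Ly49 genes are near-identical copies, which member the reads came from is uncertain. A keratocyte-like cluster led by Klra4 and Klra8 held 1.11% of the class in WT and 1.41% in KO at 2 months and 19.5% and 10.6% at 6 months. The chemokines Ccl8 (3.15), Cxcl2 (2.87) and Cxcl1 (2.49) and the early-response genes Atf3 (2.52) and Jun (1.46) rose in both genotypes. Rab6b, a GTPase of vesicle transport, fell by 5.14 on the log2 scale (± 0.490, adjusted p = 2.41e-22, -6.07 and -3.73), Igfbp7, a secreted binding protein, by 2.04 (± 0.240, adjusted p = 2.6e-14, -1.98 and -1.83) and Fmod, a collagen-binding proteoglycan, by 1.74 (± 0.283). Saa3 (9.15 ± 0.620), Lcn2 (7.30) and Chil1 (4.66) also rose, with 4.55 within WT and 11.19 within KO for Saa3. Ccl2 (-0.63 and 3.49) and Rsad2 (-6.31 and 2.17) passed the test with opposite signs.

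The edgeR test on age in keratocyte-like cells called 118 genes higher and 105 lower of 14143, with 965 at an unadjusted p under 0.05, and DESeq2 called 64, with no adjusted p for 2194 genes. In fits of age alone, the count was 10 with all 4 libraries, 133 without the 2-month WT library, 102 without the 2-month KO library, 3364 without the 6-month WT library and 863 without the 6-month KO library. The genotype and age tests shared 23 higher genes, against 0.259 for independent lists, and 2 lower, against 0.111. Both use the same 4 libraries, and a gene high in the 6-month KO library alone can be called higher in both tests. Saa3, Lcn2, Chil1 and Mmp3 were among the shared higher genes. The values for independent lists are thus no measure of the overlap to be had without a link between genotype and age.

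Among all cells, keratocyte-like cells were 70.9% in WT and 60.9% in KO at 2 months and 73.7% and 77.1% at 6 months, so the difference was -10.03 points (-11.14 to -8.92) at 2 months and 3.4 points (2.34 to 4.46) at 6 months. The 6-month difference was 0.58 points with at least 1000 UMIs per cell, -2.81 with the knee rule and -0.85 without the low-UMI cluster. Epithelial cells were 16.1% and 27.0% at 2 months, a difference of 10.85 points (9.88 to 11.82), and 13.7% and 9.68% at 6 months (-3.97 points, -4.75 to -3.18). Clusters led by Psca, with the highest depth of 9774 to 21400.5 UMIs per cell in cornea libraries, were 8.57% to 9.89% there and were left unnamed. A test of genotype in them, added after the data were seen, called 34 genes higher and 7 lower of 9677 over the 4 cornea libraries, with 367 at an unadjusted p under 0.05, and 5 higher over the 6-month pairs. Conjunctival-like cells were 0.440% to 0.928% and Schwann-like cells 0.0539% to 0.224% of cornea libraries. Dissection, digestion and the depth gap can set these shares. As Scrublet did not work on the cornea libraries, the cells of highest UMI counts may hold doublets.

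The fixed gene lists were tested with camera. In epithelial cells the stromal list was lower in KO (adjusted p = 2.23e-26, and 0.753 with an estimated correlation). Of its 18 measured members 0 were higher, 15 were lower when adjusted over the list alone and 0 over all genes. The basal (0.00743), cell cycle (0.00963, 12 of 16 members lower), resident macrophage (0.0334) and axon guidance (0.0403) lists were also lower, each at 0.753 with an estimated correlation. In all immune cells MHC class II was lower (1.83e-06, 0.849 estimated), with 8 of 9 members lower, 6 adjusted over the list alone and 0 over all genes, as H2-Aa (-0.97) and Cd74 (-0.88). There the T cell effector list was higher (0.0110, 0.849 estimated, 3 of 4 members, as Areg at 2.52) and the stromal list lower (0.0440, 0.849 estimated, 8 of 10). In keratocyte-like cells MHC class II was lower (0.000356, 0.709 estimated, 9 of 9 members). Its genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 lead the macrophage-like cluster, and free RNA as their source in keratocyte-like cells was not tested. In macrophage-like cells camera called 0 lists.

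With age, epithelial cells had the cell cycle (7.41e-34, 0.659 estimated, 16 of 16 members, 13 adjusted over the list alone and 11 over all genes), inflammatory (2.94e-09, 0.659), early-response (4.22e-06, 0.843) and basal lists (2.36e-05, 0.659) higher and the differentiated list lower (3.05e-05, 0.751). Keratocyte-like cells had the inflammatory (2.26e-26, 10 of 11 members, 7 adjusted over the list alone and 5 over all genes) and early-response lists (2.1e-07, 12 of 13) higher and the MHC class II (0.00139), differentiated (0.00139) and stromal (0.0124) lists lower, each at 0.726 with an estimated correlation. None of these calls held with an estimated correlation. That form of camera rests on the residual degrees of freedom, 1 here, so it can hardly call a list. For the cell cycle list in epithelial cells the estimated correlation was -0.05. Its unadjusted camera p was 0.0478, against 4.94e-35 at the preset correlation. The lost calls thus do not show that correlation between genes made them, nor do the preset p-values measure the spread between libraries. Complement, phagocytosis, heat shock and clock lists were called in no comparison, and of the mast cell list only Srgn was measured (0.27 in immune cells, -0.12 in macrophage-like cells). A median against the sign of its test, in each case without a call, was seen for interferon (-0.13) and targets (-0.07) in macrophage-like, phagocytosis (-0.02) and basal (0.00053) in immune, MHC class II (0.17), complement (0.42) and phagocytosis (-0.27) in epithelial, and complement (-0.03) and phagocytosis (-0.02) in keratocyte-like cells. With age the same was seen for resident macrophage (0.07) and stromal (0.05) lists in epithelial and resident macrophage (0.13) in keratocyte-like cells.

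A loss of the microRNAs would raise their direct targets. The list of proposed or reported targets was called in no test, with 18 of 24 members higher in KO keratocyte-like cells (median 0.08, as Cacna2d1 at 0.40 and Foxo3 at 0.27, adjusted p = 0.163), 6 of 23 in epithelial cells (-0.13), 6 of 12 in macrophage-like cells and 4 of 12 in all immune cells. Within the 6-month cornea pair its median in keratocyte-like cells was 0.38, at percentile 99.3 of random lists, and in epithelial cells -0.45, at percentile 0.39. Those lists were not matched on UTR length, and in keratocyte-like cells of that pair random sets matched to seed-match genes on UTR length too had a difference of medians of 0.16. For genes with a seed match in the 3' UTR, 1 of 12 pairs of class and library pair lay above the central 95% of random sets (epithelial cells in CRIC, percentile 99.9, difference of medians -0.06). With sets matched on expression alone, 5 lay above and 6 below the central range.

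**Figure D5:**
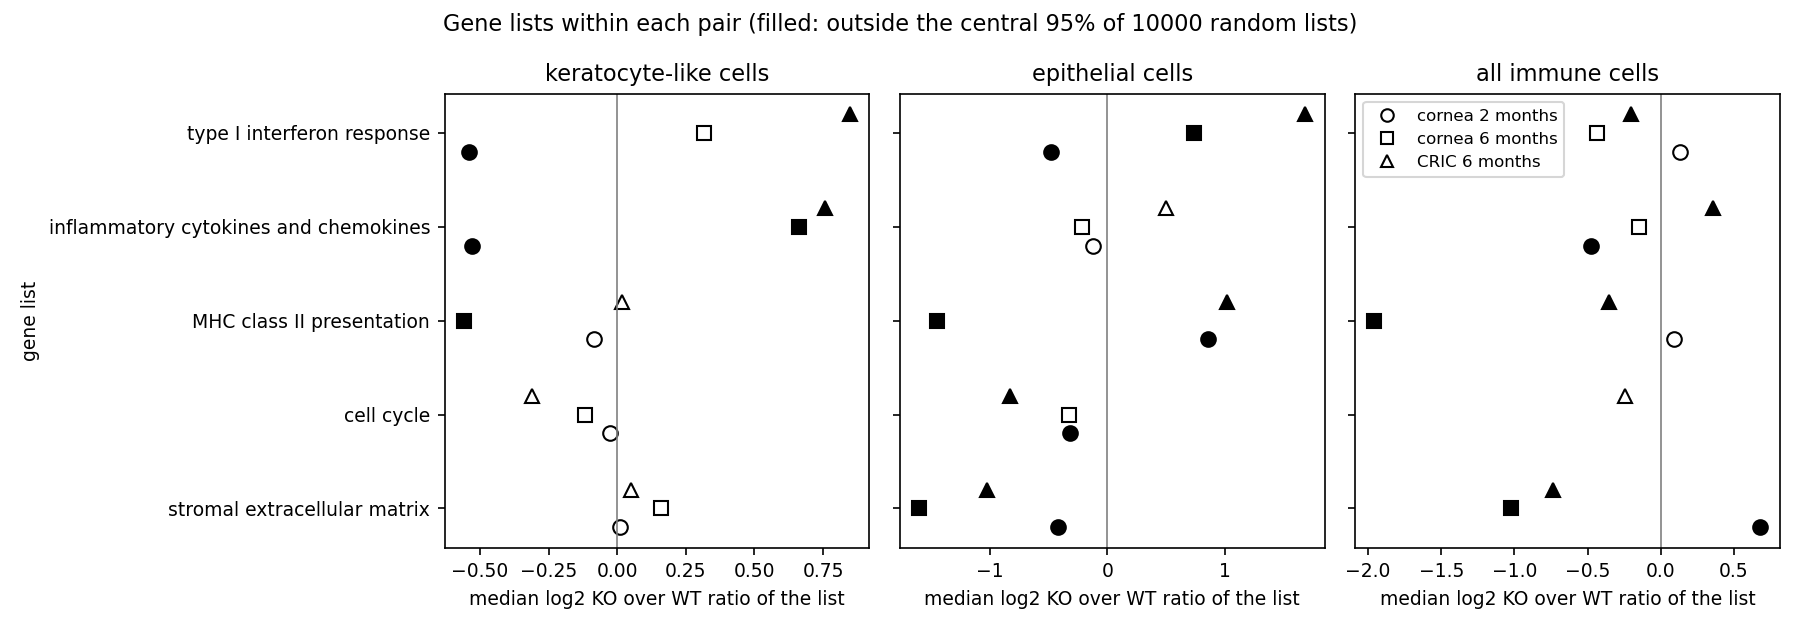
Each point gives the median log2 KO over WT ratio of a gene list in 1 class and pair, for 5 lists and 3 classes, and filled points lie outside the central 95% of 10000 random lists matched on expression (x scales differ between panels). The interferon list in epithelial cells lay at -0.48 at 2 months, 0.74 in cornea at 6 months and 1.68 in CRIC.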

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

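The rule that picked these results was set only after the lists' percentiles had been seen: a list whose median lay outside the central 95% of random lists in opposite directions in different pairs, or a gene named within pairs with opposite signs. Each pair holds 1 library per genotype. None of the differences between pairs below was tested, and no explanation for them was tested. The library labelled KO at 2 months also held Y-linked UMIs, which the other libraries all but lacked. Most of the sign changes set that pair against those of 6 months.

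The interferon list changed sign between pairs in epithelial and keratocyte-like cells. Its median log2 ratio in epithelial cells was -0.48 at 2 months, 0.74 in cornea at 6 months and 1.68 in CRIC. In keratocyte-like cells it was -0.54 at 2 months and 0.85 in CRIC, with 0.32 in cornea at 6 months inside the central 95%. Isg15, an interferon-induced ubiquitin-like protein, was at -0.77, 1.53 and 1.92 in epithelial cells of the 3 pairs. Ifitm3, which blocks entry of viruses, was at -0.80 at 2 months and 1.77 in CRIC. The difference between the pairs was not tested.

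The inflammatory cytokine and chemokine list changed sign in the same direction. In keratocyte-like cells the list's median was -0.53 at 2 months, 0.66 in cornea at 6 months and 0.76 in CRIC. In all immune cells it was -0.48 at 2 months and 0.36 in CRIC. Early-response genes went the other way in epithelial cells, with a median of 0.46 at 2 months and -0.59 in cornea at 6 months. Axon guidance genes in keratocyte-like cells had a median of 0.50 in cornea at 6 months and -0.44 in CRIC, 2 pairs of the same age. MHC class II genes, which immune cells hold at far higher levels, had a median of 0.85 at 2 months, -1.44 in cornea at 6 months and 1.02 in CRIC in epithelial cells, and of 0.16 at 2 months and -0.48 in cornea at 6 months in macrophage-like cells. These differences were not tested.

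Genes of other cell types also changed sign within immune cells. Differentiated epithelium genes had a median of 0.63 at 2 months and -1.05 in cornea at 6 months in all immune cells, and of 0.66, -0.94 and, in CRIC, -0.56 in macrophage-like cells. Stromal genes in all immune cells had a median of 0.68 at 2 months, -1.02 in cornea at 6 months and -0.74 in CRIC, and in macrophage-like cells of 0.64, -1.08 and -0.74. Yae1d1, which encodes a ribosome assembly factor, was at -4.08 at 2 months and 5.57 in cornea at 6 months in all immune cells, and at -4.01 and 5.21 in macrophage-like cells. The cornea libraries held 191 to 328 immune cells each. These differences were not tested.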

How the results depend on the processing

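Of the alternatives below, these were chosen only after the data had been seen: another Leiden seed, fits of the 6-month pairs only, adding the unnamed immune cluster, and leaving out the low-UMI keratocyte cluster or the highest doublet scores. Every cause not stated was not tested.

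In macrophage-like cells 3 genes passed between genotypes. The count was 6 with predicted doublets kept, 1 at Leiden resolution 0.5, 0 with another Leiden seed, with each cell thinned to 500 UMIs, without the pair as a block (genotype alone) and without the CRIC pair, and 1 without the 6-month cornea pair. It was 1 without the highest doublet scores, 17 with the unnamed cluster added and 95 with it in the 6-month pairs only. Leaving out 1 library each gave 1 to 4, the 1 being lower in KO. In all immune cells 27 genes passed. The count was 13 with the DESeq2 Wald test, 46 without the low-count filter, 4 with at least 1000 UMIs per cell, 0 without the block, 54 without the 2-month pair, 3 without the 6-month cornea pair, 2 without the CRIC pair and 9 to 122 without 1 library each. The labels number no replicates, so the pair block stands for age and preparation alone.

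In epithelial cells 0 genes passed between genotypes with edgeR, with 544 at an unadjusted p under 0.05, and 1 by DESeq2. The count was 153 without the low-count filter, 1 with at least 1000 UMIs, 64 with predicted doublets kept, 1 at resolution 0.5, 52 with another Leiden seed, 27 after thinning, 1 with 6 libraries and the pair as a block, 187 in the 6-month pairs only and 0 to 26 without 1 library each. In keratocyte-like cells 46 passed. The count was 0 with DESeq2, with genotype alone and with 6 libraries, 13 after thinning, 85 without the low-UMI cluster and 0 to 3 without 1 library each, in fits of genotype alone that mix the ages. Without the 6-month KO library the folds of Saa3 (-1.84), Lcn2 (-1.64), Chil1 (-0.21), Pcdh15 (-0.35) and Ccl7 (-0.53) were reversed. Their highest values without 1 library each were 11.74, 8.72, 7.31, 4.90 and 3.21. In the 6-month pairs only, Cxcl10 (0.96) and Atg2a (0.23) were reversed.

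With age 261 genes passed in epithelial cells. The count was 173 with DESeq2, 981 without the filter, 425 with at least 1000 UMIs, 1236 with predicted doublets kept, 1163 with another Leiden seed, 747 without the highest doublet scores, 114 after thinning and 152 to 2142 without 1 library each. With 1 residual degree of freedom, a small move of cells between clusters can shift the count as much. In keratocyte-like cells 223 passed with age. The count was 64 with DESeq2, 50 after thinning, 10 with age alone, 524 without the low-UMI cluster and 102 to 3364 without 1 library each. The fold of Rsad2, age, keratocyte-like cells, ran from -5.36 without the 6-month KO library to a reversed 0.82 without the 2-month WT library, and that of Ccl2 from 2.56 without the 2-month WT library to a reversed -0.0409 without the 6-month KO library. Within the 6-month cornea pair, thinning reversed Hist1h2ae in immune cells (0.80) and 1700025G04Rik in macrophage-like cells (0.19).

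Of the values over the alternatives of genes named by rule that passed the test over the libraries, none was reversed for the 2 such genes of macrophage-like cells (22 of 34 values kept their side of the test), the 16 of all immune cells (199 of 291) or the 49 with age in epithelial cells (605 of 662). For keratocyte-like cells 247 of 479 kept it between genotypes and 507 of 596 with age.

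Shares are given as KO minus WT in points. For immune cells in cornea at 6 months (1.683 in the report) the value was 1.009 with at least 1000 UMIs and 0.706 with the knee rule, and in CRIC (3.43) 22.92 and 0.69. For macrophage-like cells at 2 months (-4.17) it was -11.88 with at least 1000 UMIs, 0 with the knee rule, and reversed at 0.27 without the ambient test, 4.65 with doublets kept and 1.69 with another Leiden seed. In cornea at 6 months (-65.06) it was -5.66 with at least 1000 UMIs and -10.51 with each cell's own markers, and reversed at 11.11 with the knee rule, 2.59 with doublets kept and 0.94 with at most 10% mitochondrial UMIs. In CRIC (-25.69) it was -2.52 with at least 1000 UMIs, -29.11 with the knee rule, -23.49 without the ambient test, -7.27 with doublets kept, -8.95 with at most 10% mitochondrial UMIs, -30.89 at resolution 0.5 and -5.96 with own markers. Which clusters took the name of the class changed between these settings.

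For neutrophil-like cells in cornea at 6 months (3.831) the difference was reversed at -1.282 with at least 1000 UMIs and 0 with the knee rule. In CRIC (4.485) it was 0 with the knee rule and 2.555 with own markers. For T or innate lymphoid-like cells it was 0 with the knee rule at 2 months (3.125), and 3.824 with the knee rule and 3.284 with own markers in CRIC (5.362). For keratocyte-like cells at 2 months (-10.03) it was -8.48 with at least 1000 UMIs, -6.58 with the knee rule, -11.25 without the ambient test and -5.76 without the low-UMI cluster. At 6 months (3.4) it was 0.58 with at least 1000 UMIs, 1.92 with at most 10% mitochondrial UMIs and 1.4 with own markers, and reversed at -2.81 with the knee rule and -0.85 without the low-UMI cluster. For epithelial cells at 2 months (10.85) it was 12.82 without the ambient test and 9.22 without the low-UMI cluster, and at 6 months (-3.967) -3.03, -0.45, -2.978 and -2.34 with at least 1000 UMIs, the knee rule, at most 10% mitochondrial UMIs and no low-UMI cluster.

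With an estimated correlation camera called 0 lists in all immune, epithelial and keratocyte-like cells between genotypes and in epithelial and keratocyte-like cells with age. With so few residual degrees of freedom that form of the test could hardly call any. Against random lists not matched on expression, 3 lists had a high percentile over the 3 pairs in all immune and 3 in macrophage-like cells. For seed matches, sets matched on expression alone gave 5 percentiles above and 6 below the central 95%. Depth limits the immune classes of the cornea libraries, with 191 to 328 immune cells each, and the counts of 0 neutrophil-like cells at 2 months allow up to 1.52% in WT and 1.56% in KO (3 counts of the total).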

Other observations

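The tests of depth, of a trait of 1 library, of a changed mix of immune classes and of other splits were chosen only after the results they address had been seen, and so were the comparison with another cell class, taken up when the first test of free RNA came out close to its bound, the free-RNA bound within macrophage-like cells, the present rule for free RNA in epithelial cells and the test of its share per cell.

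Genes such as Saa3, Mmp3 and Chil1 were higher in keratocyte-like cells of the KO cornea library at 6 months. Free RNA as the source is argued against, as the 10 genes of the rule stood at a median of 2.08 times their free-RNA level in that library (quartiles 1.82 to 2.18), which met the bound of 2 but not beyond its spread, and at a median of 155.2 times their level in epithelial cells (lower quartile 104). Lower depth in KO is argued against, since their median log2 ratio was 5.71 with every cell thinned to 500 UMIs, and a trait of that library alone is argued against, since it was 2.57 in the CRIC pair. Whether the libraries of 6 months share mice is not given, so a state of 1 KO mouse stays open, as do RNA quality, the genotype and an inflammation the labels do not record. No biological explanation was tested for it.

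Genes such as Arg1 and Spp1 were higher in all immune cells of the KO CRIC library. Free RNA is argued against for the 10 genes as a group, though not for each, as they stood at a median of 2.52 times their free-RNA level (quartiles 1.95 to 3.82, 9 of 10 above 1, the lowest 0.749), again not beyond the bound by its spread, and at 51.5 times their level in keratocyte-like cells of that library (lower quartile 9.12, 7 of 10 above 1, the lowest 0.50). A trait of that library alone is argued against, as their median log2 ratio was 3.76 in the cornea pair at 6 months. By the rule, a changed mix of immune classes alone could not be told apart from a rise within macrophage-like cells. There the 10 genes had a median log2 ratio of 1.94 but stood in KO at a median of 1.099 times their free-RNA level (quartiles 0.646 to 1.92). Free RNA as the main source of that level is argued against by some genes of other cell types, though not by all. In all immune cells of that library Krt14, Chil1 and Serpina3n stood at 3.39, 3.81 and 0.212 CPM, against 124.5, 35.3 and 22.8 in free RNA. Saa3 (8.9 against 42.5) and Lcn2 (4.66 against 21.8) lay below it too, while Timp1 (8.48 against 8.30) and Slpi (10.6 against 6.22) did not. These values are not of macrophage-like cells alone. A shift between clusters of the class stays open, as the one led by Lpl held 2.39% in WT and 24.5% in KO CRIC. The genotype and a state shared by mice of 6 months stay open too, and no biological explanation was tested.

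Stromal genes such as Kera and Dcn were lower in KO epithelial cells, where their median level in WT was 0.113 times that in free RNA at 2 months and 0.142 times at 6 months. At 2 months their log2 ratio differed from that in free RNA by a median of -0.43 (quartiles -0.56 to -0.40), as much as the fall itself (-0.42), which is too small for the bound of 0.5, so free RNA cannot be told apart from a change in the cells, nor can its share per cell (0.114 for immune genes, quartiles -0.43 to 1.63). At 6 months the difference was -1.87 (quartiles -2.14 to -1.57), which by the rule set before the result argued against free RNA. That rule left out the share of free RNA per cell, which could have fallen in KO, as 12 genes of the resident macrophage and MHC class II lists fell alike, with a median difference of -1.64 (quartiles -2.19 to -0.97), although barcodes of free RNA held 8.86% of UMIs in KO and 7.58% in WT, so free RNA cannot be told apart from a change in the cells there either. Fewer doublets of epithelial cells with other cells in KO stay open, since Scrublet did not work on these libraries. Epithelial clusters that also showed keratocyte markers stayed in the class.

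A strain difference around the deleted cluster was tested on expressed keratocyte genes within 10 Mb. Of 42 near genes 1, Ptn, kept its sign with an absolute log2 above 0.5 in both cornea pairs (2.38%), against 3 of 5360 elsewhere (0.0560%), a ratio of 42.5. It rests on 1 gene, so a minimum of 3 such genes was added after it had been seen, and a strain difference cannot be told apart from chance because the counts are too few.

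The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05, and some of them break the pairs used as a block. In macrophage-like cells the real split called 3 genes and the highest other split 11, and 3 of the 10 splits, the real one among them, gave as many. That highest other split sets both 2-month libraries and the 6-month WT cornea library against the rest. With the pair as a block it rests on WT against KO in the 6-month cornea pair alone, so it is no split free of genotype. In all immune cells the real split called 27 genes and the highest other, in which the 2-month pair was turned round, 34. There 2 of the 10 splits, the real one among them, gave as many.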
